A study of Homo sapiens with 11 samples.

How the data were processed

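Punch biopsies of the buccal mucosa, the lining of the inner cheek, were profiled on 11 Affymetrix Human Genome U133 Plus 2.0 arrays. These are single-colour oligonucleotide arrays that carry several short probes, grouped into probe sets, for most human transcripts. Per the labels, 3 biopsies came from healthy people, 4 from patients with acute myeloid leukaemia (AML) before induction chemotherapy and 4 from such patients 2 days after chemotherapy, which the treatment protocol counts from its start. The patients numbered 5, of whom 3 gave a usable biopsy at both times and 2 at one time only. Per the labels' protocols, tissue was kept in an RNA-stabilising solution, total RNA was extracted with TRIzol and column purification, and biotin-labelled cRNA was hybridised. Per the submitters' processing notes, GCOS 1.2, Affymetrix's scanner and signal software, was used. Its settings are not given in the sources used here.

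The deposited table holds 1 linear intensity per probe set and array, for 54675 probe sets, without detection calls. The values show that the arrays had been brought to a common level before deposit: their 2% trimmed means lay between 477.3 and 499.6, a spread of 4.68%, and their medians between 127.6 and 142.9. The method and target of that scaling are not given in the sources used here. Of all values, 2 were below 0. On 1 post-chemotherapy array every value had at most 1 decimal, whereas on the other 10 arrays between 15.3% and 21.3% of values did, so the arrays differ in how their values were written or handled after the signal step. The arrays were not rescaled here, because the rule fixed before the data were examined asked for it only above a spread of 5%.

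Probe sets were named through the platform's annotation. Of the probe sets, 41097 carried 1 gene symbol, 1801 several and 11777 none, and only those with 1 symbol entered the gene tests. Current symbols were looked up through Entrez identifiers in a gene table of assembly GRCh38.p14, where 41043 of the 41097 were found. No genome build is named for the array values, so no coordinates are given. The 62 AFFX control probe sets and 95 sex-linked probe sets were left out of all tests. A probe set was kept when it lay above the median of its own array on at least 3 arrays, and each gene was represented by its kept probe set with the highest mean over all 11 arrays, chosen without regard to group. This left 13785 genes. Where other probe sets of a named gene differ in direction, the text says so.

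Values were analysed as log2(signal + 16). Fold changes are ratios on that scale, which understate the change of genes with low signal. Group means are given as mean ± SD on the same scale, with n biopsies. The 3 groups were fitted together in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), so that they shared 1 estimate of spread, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The comparisons were pre-chemotherapy against control, post-chemotherapy against pre-chemotherapy and post-chemotherapy against control. They share arrays, so their results are not independent of one another. The number of arrays limits the precision of every value.

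Before the data were examined, 38 gene lists were fixed, covering keratinocyte differentiation, cell cycle, stress and immune programmes and markers of the other cell types that a cheek biopsy can hold. Of their 702 members, 558 were measured, and 36 lists had at least 5 measured members (the erythroid and platelet lists did not) and were tested with limma's camera. That test compares the genes of a list with all other genes under a preset correlation between genes of 0.01. It was repeated with the correlation estimated from the data, and fry was run as a test of whether a list's genes move one way on balance. List p-values were adjusted over the 36 lists. For each list the text also counts the members that pass when p-values are adjusted over the list alone. Single values per biopsy, such as list means, were compared by two-sided exact permutation tests, whose smallest p is 0.0286 for both 3 against 4 and 4 against 4 biopsies.

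The genes named are, per comparison and direction, up to 12 with the largest change among those past the threshold, filled to 8 where fewer passed with the genes of smallest unadjusted p among those with an absolute log2 fold change of at least 1, and members with the smallest p of each list described (up to 4 after chemotherapy against before it, up to 2 in the other comparisons). Genes filled in this way did not pass. Some genes with common whole-gene deletions or copy-number variation were never named, and XIST, TSIX and Y-linked genes were neither named nor tested.

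RNA degradation was gauged by the log2 ratio of the 3' to the 5' control probe sets, averaged over GAPDH and ACTB. The patients' numbers are the same people before and after treatment, per the labels and the design text, so they pair the samples. The deviations of the 3 complete pairs from their group means correlated at 0.224, 0.0951 and 0.131. The fit with the patient as a block was run as an alternative, with a consensus correlation of 0.186. In this fit the lists were tested with cameraPR, a form of camera that works on the genes' t-statistics. List calls that it changed can therefore come from the block or from the form of the test. Other alternatives were other pseudocounts, quantile and cyclic loess normalization, other filters, every probe set tested, only the groups compared, other variance models, array weights, the RNA ratio as a covariate, and leaving out each biopsy in turn. The fits with the mean of the fibroblast list or of the T and NK cell list as a covariate, and the fit without the post-chemotherapy biopsies of highest and lowest fibroblast list mean, were added after the data had been seen.

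The fits were tested on simulated data before use, with 200 of 13785 genes changed in 10 runs. For pre-chemotherapy against control, 38.4% of genes changed by a log2 of 1 and 75.1% of those changed by 2 were recovered, and 6.09% of calls were false. For post-chemotherapy against pre-chemotherapy these values were 44.3%, 77.2% and 5.85%. For post-chemotherapy against control they were 39.8%, 75.6% and 4.98%. A list shifted by 0.4 was recovered in 10 of 10 runs for each comparison. The simulated genes varied independently, with the same spread in every group and no patient effect. These rates therefore do not cover correlated genes or unequal spread, and do not test the preset correlation of the list test.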

Results

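Gene expression was measured in buccal mucosa from 3 healthy controls, 4 patients with AML sampled immediately before induction chemotherapy, and 4 sampled after it. Induction combined cytarabine, a cytidine analogue that blocks DNA synthesis, at 100 mg/m2 for 7 days with daunorubicin, an anthracycline that traps topoisomerase II on DNA, at 45 to 60 mg/m2 for 3 days. The sample labels place the later biopsy 2 days after chemotherapy, and the treatment protocol 2 days after its start. The protocol is followed here, by which the biopsy fell within the course; counted from the end of the course, the same values would describe a later time. The study concerns oral mucositis, the injury of the mouth lining caused by chemotherapy, and its comparisons ask how the cheek lining of patients differs from that of healthy people and what alters in the first days of treatment.

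The arrays correlated with one another at 0.873 to 0.922, and no pair looked like a duplicate. The 3' to 5' signal ratio, which grows with RNA degradation, was 0.568 ± 0.113 (log2, SD, n = 3) in controls, 0.666 ± 0.147 (n = 4) before and 0.644 ± 0.244 (n = 4) after chemotherapy. Exact permutation tests of these ratios gave p = 0.429 for pre-chemotherapy against control, p = 0.886 for post-chemotherapy against pre-chemotherapy and p = 0.657 for post-chemotherapy against control. Biopsies taken after chemotherapy were the most dispersed: the median gene had an SD of 0.357 there, against 0.291 before chemotherapy and 0.223 in controls.

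Before chemotherapy, interferon-induced genes were higher as a list in the patients' mucosa than in that of controls, a call lost with an estimated correlation (adjusted p = 0.478) and in fry (adjusted p = 0.797). Of the 30 measured members of the interferon response list 29 were higher, by 1.46-fold on average, and all 4 patient biopsies lay above all 3 controls (list mean 9.56 ± 0.187, n = 4, against 9.01 ± 0.0453, n = 3). The immediate early genes FOS and EGR1, transcription factors induced within minutes of a stimulus, had 8.10-fold and 6.80-fold higher means. The 2 other EGR1 probe sets rose less, by a log2 of 1.09 and 1.79 against 2.765. The skeletal muscle, fibroblast and epidermal-type cornification lists were lower, calls that were also lost with an estimated correlation (adjusted p = 0.478, 0.599 and 0.478). None of the 13785 genes passed the threshold in limma. At an unadjusted p under 0.05 there were 563 genes, 235 higher and 328 lower, where chance alone gives 689.

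The interferon list had a camera adjusted p of 1.01e-06 (adjusted p = 0.478 with an estimated correlation). Among its members IRF7, which drives type I interferon production, was 1.73-fold higher (adjusted p = 0.999) and the antiviral RNA sensor OAS2 was 1.89-fold higher, in 4 of 4 biopsies. No member passed, adjusted over the list alone or over all genes. The mean of the list for all 35 ways to split these 7 biopsies gave an exact permutation p of 0.0286. The MHC class I presentation list also rose, with 11 of 11 members higher by 1.29-fold on average (adjusted p = 0.018, and adjusted p = 0.742 with an estimated correlation). Its members PSMB9, an immunoproteasome subunit, and HLA-F were 1.68-fold and 1.57-fold higher, with 1 other HLA-F probe set going the opposite way. The monocyte and macrophage list (13 of 16 higher, adjusted p = 0.0388, and adjusted p = 0.796 with an estimated correlation) and the neutrophil list (7 of 8 higher, adjusted p = 0.0245, and adjusted p = 0.478 with an estimated correlation) moved the same way. The complement subunit C1QB was 2.30-fold, the scavenger receptor CD163 2.09-fold, and the neutrophil receptors FPR1 and CSF3R 1.94-fold and 1.53-fold higher. No member of these 3 lists passed adjusted over the list alone. Leaving out 1 biopsy ended the calls of the MHC class I list (control replicates C1 or C3 or pre-chemotherapy replicate 2, adjusted p up to 0.217), the monocyte list (C1, C2 or pre-chemotherapy replicates 1, 2 or 5, up to 0.229) and the neutrophil list (C1, C3 or pre-chemotherapy replicate 4, up to 0.239), and the monocyte call was also lost with the patient as a replicate block (adjusted p = 0.0691).

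In the immediate early list 16 of 19 members were higher (adjusted p = 0.00239, and adjusted p = 0.478 with an estimated correlation). Adjusted over the list alone, 2 rose and 1 fell, and over all genes none passed. FOS stood at 10.7 ± 1.34 (n = 4) against 7.71 ± 0.38 (n = 3) in controls, higher in 4 of 4 biopsies. EGR1 stood at 12.7 ± 1.89 (n = 4) against 9.92 ± 0.0948 (n = 3), higher in 3 of 4. The member that fell adjusted over the list alone was the early response gene IER3, 0.565-fold of control. Without pre-chemotherapy replicate 2, the biopsy that lay at the control level, EGR1 passed among all genes (adjusted p = 0.000635, with 3.71 as the log2 fold change). This was the only 1 of 22 alternatives in which it passed. Because that fit leaves out the biopsy without the rise, the call does not add support. The unfolded protein and integrated stress list rose by 1.24-fold on average (14 of 17 higher, adjusted p = 0.000125, and adjusted p = 0.478 with an estimated correlation), and the chaperone CALR, 1.60-fold higher, passed adjusted over the list alone. The disulphide isomerase PDIA4 was 1.36-fold higher, though its other probe set differed in direction. The glucocorticoid target list rose as well (10 of 11 higher, adjusted p = 0.00239, and adjusted p = 0.478 with an estimated correlation), with MT1X, a metallothionein, 1.27-fold and KLF9 1.50-fold higher (1 other KLF9 probe set was lower) and no member passing adjusted over the list alone. The immediate early call was lost without control replicate C3 or pre-chemotherapy replicate 4 (adjusted p up to 0.144), and the glucocorticoid call without control replicate C1 or pre-chemotherapy replicate 4 (up to 0.208).

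Genes of dividing cells were slightly higher on average in the patients, but not in every biopsy. Exact permutation tests of the list means gave p = 0.143 for the mitotic and 0.257 for the DNA replication list. The mitotic list rose by 1.16-fold on average with 24 of 26 members higher (adjusted p = 2.39e-05, and adjusted p = 0.478 with an estimated correlation), and the DNA replication list by 1.12-fold with 20 of 27 higher (adjusted p = 0.00655, and adjusted p = 0.599 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, was 1.47-fold and the cyclin CCNB2 1.33-fold higher. RRM2, a ribonucleotide reductase subunit, was 1.73-fold and the licensing factor CDC6 1.93-fold higher, and the other CDC6 probe set went the opposite way. The other RRM2 probe set rose less, by a log2 of 0.195 against 0.7866. Only 1 of 4 biopsies had CDC6 above every control (control SD 1.15), and without control replicate C2 its log2 fold change was 0.3077 in place of 0.9515. Adjusted over the list alone, no member of either list passed. The replication call was lost without control replicate C1 or pre-chemotherapy replicates 2 or 5 (adjusted p up to 0.155).

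Lower in the patients were the skeletal muscle list (13 of 14 members lower, 0.405-fold on average, adjusted p = 6.09e-05, and adjusted p = 0.478 with an estimated correlation), the fibroblast and matrix list (19 of 20 lower, 0.612-fold, adjusted p = 0.000396, and adjusted p = 0.599 with an estimated correlation) and the smooth muscle and pericyte list (7 of 8 lower, 0.738-fold, adjusted p = 0.049, and adjusted p = 0.478 with an estimated correlation). The contractile gene ACTA1, at 5.463 a dim signal in the patients, was lower on average, but in 0 of 4 biopsies below every control (control SD 3.49), with a log2 fold change of -1.561 without control replicate C2 and -5.047 without C3. NEB was 0.430-fold of control (log2 fold change -1.218, and -0.5132 without C2), the matricellular protein POSTN 0.422-fold, FBLN1 0.617-fold, the muscle filament DES 0.273-fold and ACTA2 0.655-fold. Skeletal muscle genes varied widely among controls, with a list mean of 8.13 ± 1.76 (n = 3) against 6.82 ± 0.217 (n = 4), and the call was lost without control replicate C2 (adjusted p = 0.303). The cornifying list (12 of 14 lower, adjusted p = 0.00239, and adjusted p = 0.478 with an estimated correlation) and the desmosome list (11 of 16 lower, adjusted p = 0.0284, and adjusted p = 0.478 with an estimated correlation) fell too. Their members FLG, the filament-aggregating protein of cornified cells, DSG1, DSP and CLDN1 were 0.390-fold, 0.705-fold, 0.859-fold and 0.732-fold of control, and the other CLDN1 probe set did not follow. No member of these 5 lists passed adjusted over the list alone. Leaving out 1 biopsy also ended the calls of the cornifying list (C2 or pre-chemotherapy replicate 1, adjusted p up to 0.142), the desmosome list (C1, C2 or pre-chemotherapy replicates 4 or 5, up to 0.105) and the smooth muscle list (C1, C3 or pre-chemotherapy replicates 2 or 5, up to 0.239), the last of which was lost with the replicate block too (adjusted p = 0.0539).

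Of the single genes with the smallest p and at least a doubling, CEACAM7, IRAG2, RPLP2, MAB21L3, MEI1 and TYMSOS were higher, by 5.86-fold, 3.96-fold, 2.13-fold, 3.23-fold, 2.24-fold and 2.93-fold. SAMD4A, an RNA-binding translational repressor, had the smallest p among the lower genes (0.456-fold, adjusted p = 0.432). PFKFB2, an enzyme that sets the rate of glycolysis, was 0.499-fold of control, with 1 other probe set going the opposite way, and the epithelial sodium channel subunit SCNN1G was 0.390-fold. NDRG4, RUSC2, LINC01214, KLHL41 and KRT33B were 0.478-fold, 0.273-fold, 0.439-fold, 0.174-fold and 0.182-fold. None passed the threshold. The control means of IRAG2, RPLP2, MAB21L3, MEI1 and TYMSOS (6.07 to 6.82) lay below every array median, as did the patient means of RUSC2, KLHL41 and KRT33B (6.06 to 6.56). Folds from such dim signals depend most on the pseudocount. The other IRAG2 probe set rose less, by a log2 of 0.454 against 1.984. RPLP2 encodes a ribosomal protein, yet its probe set read 7.851 in patients and 6.764 in controls. The list of other cytosolic ribosomal protein genes had a mean of 15.54. The RPLP2 fold therefore cannot be taken as a change in an abundant ribosomal transcript.

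**Figure D1:**
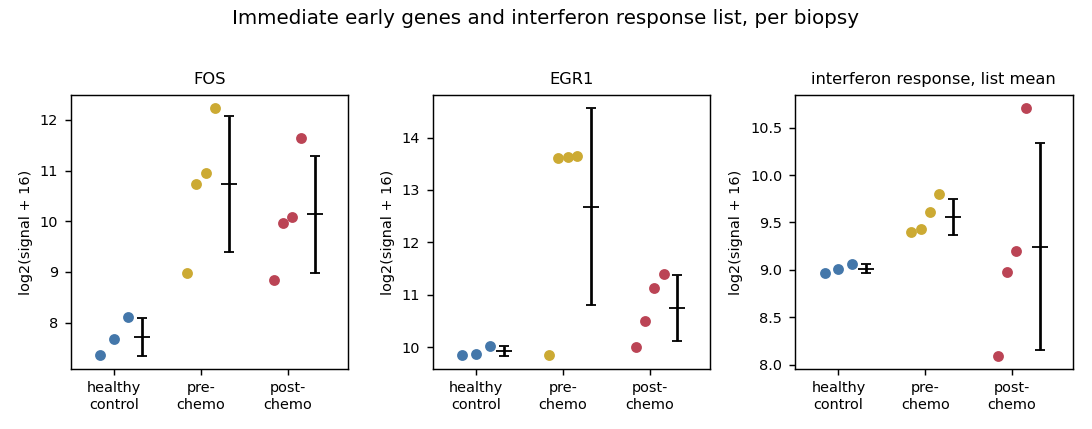
FOS, EGR1 and the mean of the interferon response list in each biopsy, as log2(signal + 16), for healthy controls (n = 3), patients before (n = 4) and patients after chemotherapy began (n = 4); dots are biopsies, and the horizontal tick with its bar is the mean ± SD. FOS lies above every control in all 4 pre-chemotherapy biopsies and EGR1 in 3 of 4, and the interferon list mean, 9.56 before chemotherapy and 9.01 in controls, is most widely spread after it (SD 1.09). FOS also lies above every control in the post-chemotherapy biopsies (8.846 to 11.65 against 7.352 to 8.11).

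After chemotherapy had begun, genes activated by the tumour suppressor p53 rose together. Mitotic genes fell as a list, to 0.707-fold with 26 of 26 members lower, a call lost in the stricter test (adjusted p = 0.177 with an estimated correlation). MDM2, the ubiquitin ligase that p53 induces and that degrades p53, rose 2.19-fold (11.7 ± 0.193, n = 4, against 10.5 ± 0.179, n = 4, adjusted p = 0.0358) and was higher in 4 of 4 biopsies than in any biopsy taken before treatment. All 5 other MDM2 probe sets were higher too. The p53 target list rose by 1.39-fold on average with 23 of 27 members higher. MDM2 was the only gene past the threshold in limma among 13785. At an unadjusted p under 0.05 there were 998 genes, 322 higher and 676 lower, where chance gives 689.

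The p53 target list (adjusted p = 2.68e-17) held with an estimated correlation (adjusted p = 0.000313) and in fry (adjusted p = 5.96e-05). Adjusted over the list alone 11 of its 27 members rose and 0 fell, and 1 rose over all genes. The list mean was 10.4 ± 0.0494 (n = 4) against 9.93 ± 0.0186 (n = 4), with every later biopsy above every earlier one (exact permutation p = 0.0286). In the 3 patients sampled at both times the list mean rose by 0.473 to 0.506. TRIAP1, an inhibitor of apoptosis, was 1.77-fold higher (adjusted p = 0.0511), SPATA18, which acts in mitochondrial quality control, 2.35-fold (adjusted p = 0.114), TIGAR, a regulator of glycolysis, 2.15-fold (adjusted p = 0.142) and POLH, the polymerase that copies past DNA lesions, 2.40-fold (adjusted p = 0.173).

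The mitotic list (adjusted p = 4.45e-12) passed in fry (adjusted p = 0.03) but not with an estimated correlation (adjusted p = 0.177). Adjusted over the list alone 3 of its 26 members fell, and none over all genes. CDC20 stood at 0.493-fold (adjusted p = 0.142), the spindle protein DLGAP5 at 0.389-fold (adjusted p = 0.173), the proliferation marker MKI67 at 0.621-fold (adjusted p = 0.36) and NUSAP1 at 0.731-fold, its other probe set being slightly higher. The list mean was 8.83 ± 0.158 (n = 4) against 9.33 ± 0.199 (n = 4), lower in 4 of 4 biopsies (exact permutation p = 0.0286), and in the 3 complete patients it fell by 0.242 to 0.758. The DNA replication list, with 19 of 27 members lower and a mean of 0.885-fold, did not pass (adjusted p = 0.183).

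**Figure D2:**
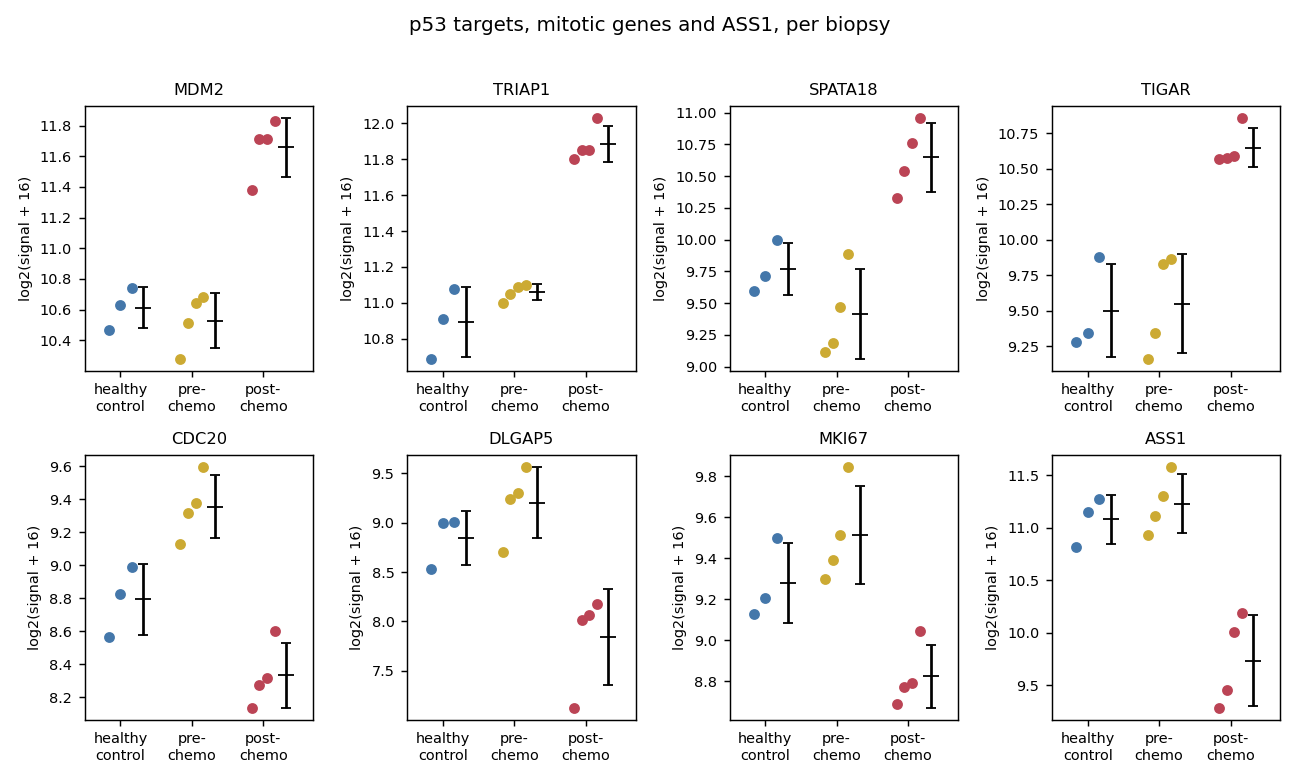
Signal of 4 p53 targets (MDM2, TRIAP1, SPATA18 and TIGAR), 3 mitotic genes (CDC20, DLGAP5 and MKI67) and ASS1 in each biopsy, as log2(signal + 16), by group (n = 3, 4 and 4); dots are biopsies, and the horizontal tick with its bar is the mean ± SD, on axes that do not start at 0. For each gene the 4 post-chemotherapy biopsies lie wholly above or wholly below the 4 pre-chemotherapy ones, as for MDM2 at 11.7 against 10.5 on average.

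Connective tissue and vessel markers were lower on average in the later biopsies, but not in every patient. Exact permutation tests of the fibroblast and endothelial list means gave p = 0.429 and 0.2. For each list 2 of the 4 later biopsies lay below every earlier one. The fibroblast and matrix list fell to 0.638-fold with 19 of 20 members lower (adjusted p = 0.00323, and adjusted p = 0.783 with an estimated correlation), and the endothelial list to 0.717-fold with 16 of 17 lower (adjusted p = 0.00323, and adjusted p = 0.687 with an estimated correlation). FBLN1, SPARC, the collagen-binding proteoglycan DCN and VIM were 0.475-fold, 0.569-fold, 0.496-fold and 0.618-fold. The endothelial transcription factor ERG was 0.504-fold, and VWF, ACKR1 and CLDN5 0.730-fold, 0.600-fold and 0.416-fold. No member of either list passed adjusted over the list alone. The fibroblast list mean spanned 8.32 to 11.4 after chemotherapy and 9.88 to 10.7 before it, and both calls were lost without post-chemotherapy replicate 4 (adjusted p = 0.449 and 0.0955). Leaving out single biopsies moved the fibroblast median shift of -0.745 to between -1.27 and -0.264. The endothelial median shift of -0.454 moved to between -0.681 and -0.293. In the 3 complete patients the fibroblast list mean changed by -1.57 to 0.647 and the endothelial by -0.804 to 0.0248, each higher in 1 of 3. Within the 3 complete patients as a fixed replicate block the endothelial call was lost as well (adjusted p = 0.0925).

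The cornifying list rose by 1.56-fold on average with 10 of 14 members higher (adjusted p = 0.0237, and adjusted p = 0.687 with an estimated correlation) and no member passing adjusted over the list alone. LCE3D, KRT2, the protease KLK7 and DSG1 were 3.64-fold, 3.70-fold, 2.23-fold and 1.37-fold higher. In the complete patients the list mean changed by -0.488 to 2.23, higher in 1 of 3. Between the groups its exact permutation p was 0.457. The rise rested on post-chemotherapy replicate 2, without which the median shift was -0.0196 (adjusted p = 0.441), and the call was also lost without pre-chemotherapy replicate 1 and within the 3 complete patients as a fixed replicate block (adjusted p = 0.0925). The T and NK cell list mean was 9.80 in post-chemotherapy replicate 2 and between 7.00 and 7.08 in the other 3, and its MHC class I list mean was 12.6 against 10.5 to 10.8. Neither list passed between the groups (adjusted p = 0.302 and 0.569).

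**Figure D3:**
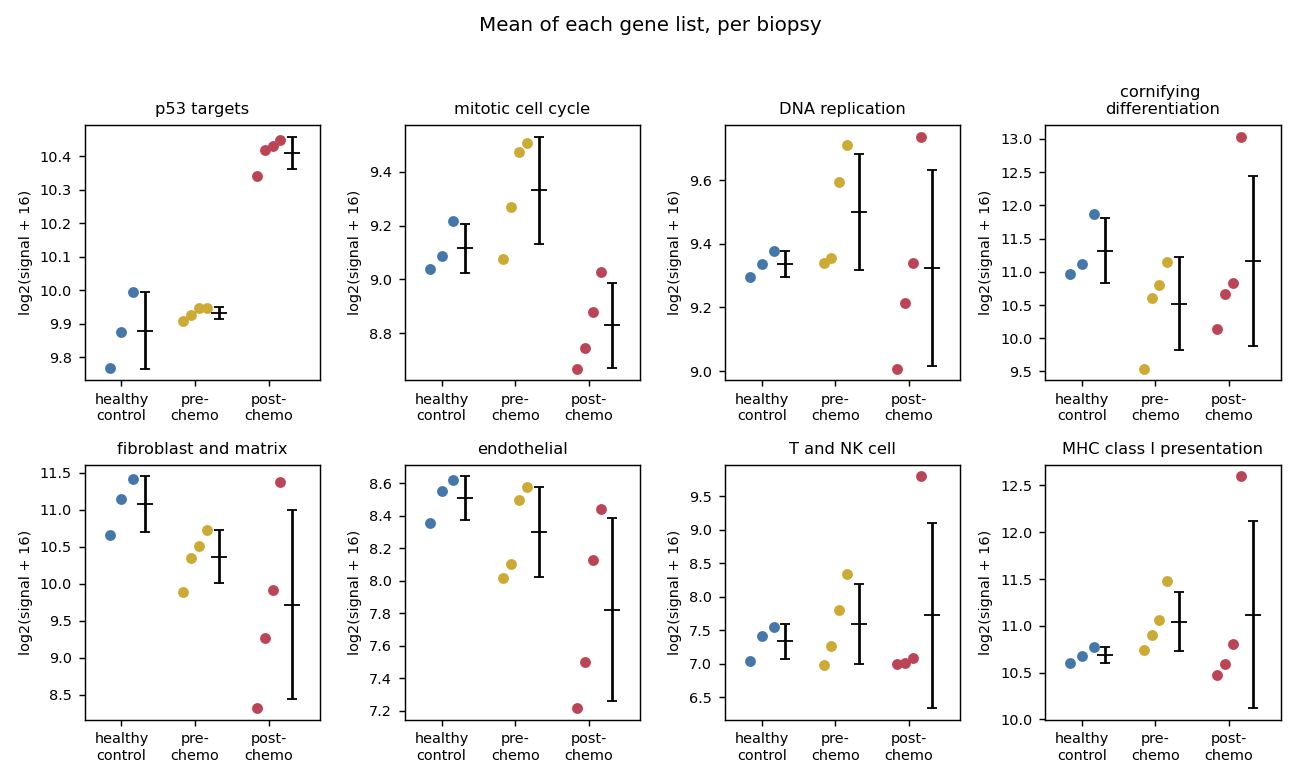
Mean of 8 gene lists in each biopsy, as log2(signal + 16), by group (healthy control n = 3, pre-chemotherapy n = 4, post-chemotherapy n = 4); dots are biopsies, and the horizontal tick with its bar is the mean ± SD, on axes that do not start at 0. The p53 target means after chemotherapy lie close together (SD 0.0494) above all others, whereas the fibroblast (SD 1.28) and T and NK cell (SD 1.39) means spread widely within the same 4 biopsies.

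Among single genes, SLC16A9, a carnitine transporter, was 2.46-fold higher (adjusted p = 0.0511) and the carbonic anhydrase CA2 3.24-fold (adjusted p = 0.142). The cytolinker EPPK1 was 6.80-fold higher and the phosphatase INPP5D 2.14-fold. The 2 other EPPK1 probe sets rose by a log2 of 0.534 and 2.4, against 2.766. ASS1, which makes the precursor of arginine, was 0.356-fold (9.74 ± 0.433, n = 4, against 11.2 ± 0.28, n = 4, adjusted p = 0.0511). H6PD, ST6GAL2, the pericyte gene RGS5 and CLDN8 were 0.407-fold, 0.396-fold, 0.413-fold and 0.380-fold, with 1 RGS5 probe set going the opposite way. GRPR was lower too, but at 5.18 its later signal was dim, and its log2 fold change of -2.637 became -3.38 with a pseudocount of 1 and -1.684 with 64. With the patient as a replicate block 4 genes passed, TRIAP1 (adjusted p = 0.0279), SLC16A9 (adjusted p = 0.0326) and ASS1 (adjusted p = 0.0408) joining MDM2, and within the 3 complete patients as fixed blocks none did. The MDM2 call was lost in 6 of 8 fits that left out 1 biopsy, those without pre-chemotherapy replicates 1, 2, 4 or 5 or post-chemotherapy replicates 3 or 4 (adjusted p = 0.0722 to 0.158, log2 fold change 1.049 to 1.18). In these 0 genes passed, except without pre-chemotherapy replicate 2, where 1 other gene did, while 19 genes passed without post-chemotherapy replicate 2.

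Set against healthy mucosa, the biopsies taken after chemotherapy began had higher p53 targets, and lower stromal lists whose calls were lost with an estimated correlation (adjusted p = 0.359 to 0.709). POLH, MDM2, TRIAP1 and RPS27L, a p53-regulated ribosomal protein, rose 3.50-fold, 2.06-fold, 1.99-fold and 1.81-fold, and the nuclear import receptor TNPO1 rose 1.93-fold. The RNA-binding protein MEX3D fell to 0.470-fold and SPTBN1, a spectrin of the membrane skeleton, to 0.537-fold. Each of these 7 genes, the only ones past the threshold (adjusted p = 0.0406 to 0.0425), was beyond all controls in 4 of 4 biopsies. At an unadjusted p under 0.05 there were 1403 genes, 421 higher and 982 lower, where chance gives 689. The post-chemotherapy arrays are those of the preceding comparison, so the p53 genes are not a second, independent observation.

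The p53 target list rose by 1.45-fold with 24 of 27 members higher (adjusted p = 8.94e-16, and adjusted p = 0.000442 with an estimated correlation), and 11 members rose adjusted over the list alone. Over all genes 3 of them passed (POLH, MDM2 and TRIAP1), and RPS27L was not on the list. Of the other rising lists, the unfolded protein and integrated stress list was 1.23-fold with 15 of 17 higher (adjusted p = 0.000294, and adjusted p = 0.359 with an estimated correlation), with ATF3 1.78-fold and DDIT3 3.36-fold. The oxidative phosphorylation list was 1.05-fold with 21 of 28 higher (adjusted p = 0.0145, and adjusted p = 0.722 with an estimated correlation), with NDUFB5 1.17-fold and ATP5MC1 1.40-fold, and was lost without control replicate C1 or post-chemotherapy replicate 3 (adjusted p up to 0.352). The MHC class I list (10 of 11 higher, adjusted p = 0.0145, and adjusted p = 0.722 with an estimated correlation) and the interferon list (19 of 30 higher, adjusted p = 0.0145, and adjusted p = 0.722 with an estimated correlation) rested on post-chemotherapy replicate 2, without which their median shifts were 0.0151 (adjusted p = 0.981) and -0.14 (adjusted p = 0.754). TAP1 and PSMB9 were 2.12-fold and 1.80-fold, HERC6 1.55-fold and USP18 0.359-fold of control. No member of these 4 lists passed adjusted over the list alone.

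Stromal lists fell against controls: fibroblast and matrix to 0.390-fold with 20 of 20 members lower (adjusted p = 4.26e-08, and adjusted p = 0.709 with an estimated correlation), smooth muscle and pericyte to 0.560-fold with 7 of 8 lower (adjusted p = 0.000819, and adjusted p = 0.359 with an estimated correlation) and endothelial to 0.621-fold with 15 of 17 lower (adjusted p = 0.000819, and adjusted p = 0.709 with an estimated correlation). Adjusted over the list alone 1, 5 and 0 members fell, and none over all genes. Below every control lay 3, 4 and 3 of the 4 biopsies (exact permutation p = 0.143, 0.0571 and 0.143), and the fibroblast list mean of post-chemotherapy replicate 2, at 11.37, lay within the control range of 10.66 to 11.41. FBLN1 and SPARC were 0.293-fold and 0.443-fold, RGS5 and NOTCH3 0.381-fold and 0.588-fold, ERG and TEK 0.472-fold and 0.622-fold. The skeletal muscle list (13 of 14 lower, adjusted p = 0.0439, and adjusted p = 0.722 with an estimated correlation), with NEB and TNNI2 0.433-fold and 0.510-fold, was no longer called with the replicate block (adjusted p = 0.0637, median shift -0.998). It was also lost without control replicate C2 or post-chemotherapy replicates 2, 3 or 4 (adjusted p up to 0.77). Leaving out single biopsies gave it median shifts from -1.95 to -0.0204. The mitotic list fell to 0.821-fold with 23 of 26 lower (adjusted p = 0.0171, and adjusted p = 0.722 with an estimated correlation), with DLGAP5 0.499-fold and MKI67 0.730-fold. The list of genes that handle pyrimidines and anthracyclines fell to 0.807-fold with 14 of 15 lower (adjusted p = 0.0342, and adjusted p = 0.359 with an estimated correlation), with the nucleotide kinase CMPK1 (log2 fold change -0.27) and the nucleotidase NT5E (-0.84) among them. No member of these last 3 lists passed adjusted over the list alone. The mitotic call was lost without control replicate C1 or post-chemotherapy replicates 2 or 3 (adjusted p up to 0.138), and the pyrimidine call without C1 or post-chemotherapy replicates 2 or 4 (up to 0.194).

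Further genes with small p that did not pass were MAB21L3 (6.08-fold), the death receptor TNFRSF10A (2.15-fold) and LAMP3 (3.82-fold), each at adjusted p = 0.0839, and H6PD and ASS1 (0.361-fold and 0.394-fold, also 0.0839). CREB5, SLC4A4, CDC42EP5 and TMEM47 were 0.360-fold, 0.344-fold, 0.447-fold and 0.369-fold (adjusted p = 0.146), and other probe sets of CREB5 and SLC4A4 included 1 each that went the opposite way, as did 1 each for TNPO1 and RPS27L. The count of 7 genes was sensitive to single biopsies: it was 161, 37 of them higher, without post-chemotherapy replicate 2, 1 without control replicate C1, and 0 without any other one of control replicates C2 and C3 or post-chemotherapy replicates 3, 4 and 5. The 7 genes were among the 161. It was also 0 with the RNA ratio as a covariate, where the adjusted p of the 7 was 0.0671 to 0.0825 and their median absolute log2 fold change 0.96 (median SE 0.145), against 0.991 (median SE 0.137) without it, so the calls ended with a slightly larger error at a similar change. With the fibroblast list mean as a covariate 9 genes passed, none of them among the 7, whose adjusted p was 0.0532 to 0.0724: their median absolute log2 fold change was 0.91 (median SE 0.17). With cyclic loess normalization 4 genes passed, 4 higher and 0 lower.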

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

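All tests of explanations in this part were chosen after the results had been seen, and the fits within 2 groups were added after those over all 11 biopsies. Reported results were checked in each patient group of 4. Chance sets about 1 in 20 such groups apart, and in 14 of 224 checks 1 biopsy lay far from the other 3. The gap as a share of the range is given for each.

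In post-chemotherapy replicate 2, TAP1 was high (0.902; 12.3 against 9.40 to 9.69), the MHC class I list mean was high (0.839), and SLC4A4 (0.918) and NDUFB5 (0.879) were low. Elsewhere after chemotherapy CCNB2 (0.861) and TIGAR (0.95) were high and DSP (0.887) low in replicate 4, CDC6 was low (0.967) and the neutrophil list mean high (0.863) in replicate 5, and DLGAP5 was low (0.845) in replicate 3. Before chemotherapy EGR1 was low in replicate 2 (0.994; 9.85 against 13.6), EPPK1 high in replicate 5 (0.879), and RUSC2 (0.87) and the neutrophil list mean (0.898) high in replicate 4. The filter kept 6001 probe sets that name no single gene and so entered no gene test. Fitted apart, 1 of them passed the threshold before chemotherapy against control, 1 after it against control, and 0 after it against before.

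The first pattern is the rise of p53 targets after chemotherapy began. With the fibroblast list mean as a covariate its mean shift was 0.477 (SE 0.0531), with the T and NK cell list mean 0.476 (SE 0.0478), and after quantile normalization 0.471 (SE 0.0518), against 0.478 as reported, and 0.471 to 0.487 within the 8 biopsies alone. The fibroblast fit argues against a lower stromal share as the whole cause. The arrays had already been brought to trimmed means within 4.68% of one another. Quantile normalization could therefore hardly alter the shift and says little about the scaling. The T and NK cell list mean hardly differed between these groups (mean shift 0.13, exact permutation p = 0.914), so that covariate could hardly alter the shift. No other immune list was used as a covariate for this pattern, so a part played by other immune cells was not tested. In the 35 splits of these 8 biopsies only the real 1 gave so large a shift (0.478, highest other 0.283). That is the smallest share 35 splits can give, for a list singled out after its result was seen. Adjusted over the 36 lists, the exact permutation p of its mean was 0.515, so this test alone does not exclude chance. Adjusted in the same way, the list passed with an estimated correlation (adjusted p = 0.000313) and in fry (adjusted p = 5.96e-05). Among the 8 splits that part all 3 pairs only the real 1 was as large (highest other 0.263), again the smallest share they can give. A direct p53 response to the drugs is consistent with these values and remains a hypothesis, since days of illness, other drugs and biopsy timing go with treatment and were not tested.

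The second pattern is the higher interferon list in patients before treatment, in 4 of 4 biopsies above all controls. The shift of 0.546 exceeded every other of the 35 splits (1 split as large, highest other 0.505). That is the smallest share 35 splits can give, for a list singled out after its result was seen. Adjusted over the 36 lists, the exact permutation p of its mean was 0.343, so chance is not excluded. Nor did the list pass with an estimated correlation (adjusted p = 0.478) or in fry (adjusted p = 0.797). With the T and NK cell and the macrophage list means as a covariate it was 0.352 (SE 0.344), and with the RNA ratio 0.516 (SE 0.567), errors too wide to decide because they include the dispersed post-chemotherapy biopsies. Within the 7 biopsies compared, the shifts were 0.616 (SE 0.127) and 0.451 (SE 0.0652), which argues against immune cells or RNA degradation as the whole cause. This rests on the narrower fit, and the immune covariate moved the shift in opposite directions in the 2 fits, so a part played by immune cells stays open. The RNA ratio differed little between these groups (0.0979, exact permutation p = 0.429), which makes its covariate a weak test. Leukaemia and infection could not be tested, as no label divides the patients.

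The third pattern is the higher FOS and EGR1 before treatment, which was not confined to that time. After chemotherapy began FOS still lay above every control (8.846 to 11.65 against 7.352 to 8.11). EGR1 then lay at 9.998 to 11.39, against 9.855 to 10.03 in controls. With the RNA ratio as a covariate the log2 fold change of FOS before treatment against control was 3.1 (SE 0.732), against 3.02 without it. The ratio differed little between these groups (0.0979, exact permutation p = 0.429), so that covariate could hardly alter the change and says little about degradation. The other 17 immediate early genes had a median shift of 0.228 (14 higher, 3 lower, from -0.824 to 1.02). Different handling of patient and control biopsies cannot be told apart from biology here, since such genes respond to both within minutes and no label gives the time from biopsy to preservation.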

How the results depend on the processing

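The covariate fits on list means and the fit without 2 post-chemotherapy biopsies were chosen after the data had been seen. Of 3023 recomputed fold changes, list shifts and ratio differences, 2716 kept their direction and their call or lack of one. Of 128 recomputed counts of calls 69 stayed within 1.5 times, which does not say that the same genes or lists were called. The p53 target list passed in 19 of 19 alternatives after chemotherapy against before (median shift 0.339 to 0.478) and in 17 of 17 against control (0.363 to 0.602). The mitotic list after chemotherapy against before passed in 18 of 19, all but the estimated correlation. The cause of the changes below was not tested, except that fewer biopsies or more tests lower the power. Absolute detection was not analysed here, and genes below the array medians of 127.6 to 142.9 are the least certain. Of 110 named fold changes 20 rest on a group mean below every array median, where the fold depends most on the pseudocount. Before chemotherapy against control these were IRAG2, RPLP2, MAB21L3, MEI1, TYMSOS, RUSC2, KLHL41, KRT33B, CDC6, FPR1, DES and ACTA1. After it against before they were GRPR, ERG and CLDN5, and against control MAB21L3, CREB5, USP18, ERG and DDIT3.

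Genes past the threshold before chemotherapy against control numbered 0 in every alternative except leaving out single biopsies (0 to 1). After chemotherapy against before, the count of 1 became 2 with quantile normalization, no filter or array weights, 4 with the stricter filter, robust variances, a threshold of 0.10 or the replicate block, 2 with the replicate block and RNA ratio, 3 with the fibroblast covariate, 16 with the T and NK covariate, 4 without the 2 biopsies (MDM2 not among them, adjusted p = 0.0892), and 0 with every probe set, only the 2 groups, no trend, the RNA ratio or the patient as a fixed block in 3 complete pairs. Leaving out single biopsies gave 0 to 19 and lost MDM2 in 6 of 8 fits. Over the 24 alternatives that gave an MDM2 value, the RNA ratio among them, its log2 fold change stayed between 1.049 and 1.223. The fits of every probe set and of the fixed block are not among the 24. Against control, the count of 7 became 4 with quantile or cyclic loess normalization, 1 with no filter, 0 with every probe set, only the 2 groups, no trend, or the RNA ratio with or without the replicate block, 18 with array weights, 17 at 0.10, 9 with the fibroblast covariate (0 of the 7 shared), 77 with the T and NK covariate (7 shared), 32 without the 2 biopsies (4 shared), and 0 to 161 without single biopsies. Leaving out 1 biopsy moved 26 of 110 named log2 fold changes by over 1.5 times, none of them past the threshold and none turning in sign. Before chemotherapy these were KLHL41, CDC6, ACTA1, ACTA2 and NEB (without C2), IRF7 and KLF9 (C1), POSTN, FBLN1, FPR1 and ACTA1 (C3), CD163, FPR1 and CSF3R (pre-chemotherapy replicate 4), HLA-F (2) and MT1X (1). After it against before they were LCE3D, KRT2, KLK7 and VIM (post-chemotherapy replicate 2), LCE3D, FBLN1, DCN, VIM, ACKR1 and CLDN5 (4), KLK7 (pre-chemotherapy replicate 1) and LCE3D (4), and against control HERC6, TAP1 and PSMB9 (post-chemotherapy replicate 2) and NEB (C2).

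Lists past the threshold numbered 14 before chemotherapy against control, 0 with an estimated correlation or fry, and 7 to 13 without single biopsies. After it against before, the 5 became 1 with an estimated correlation, 2 with fry, 10 with the fixed patient block, 14 with the fibroblast covariate, 9 without the 2 biopsies and 5 to 13 without single ones. Against control, the 11 became 1 with an estimated correlation or fry, 7 with the T and NK covariate, and 7 to 16 without single ones. The replicate block, whose lists were tested with cameraPR in place of camera, ended the calls of the monocyte (adjusted p = 0.0691) and smooth muscle (0.0539) lists before chemotherapy and of skeletal muscle after it against control (0.0637). After chemotherapy against before it added the stress keratin (higher, 0.0379) and smooth muscle (lower, 0.0376) lists, and it changed no other list call. Without the block neither of these 2 lists passed with an estimated correlation (adjusted p = 0.373 and 0.687). In the complete patients each list mean was higher in 1 of 3.

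Direction turned in these. With the fibroblast covariate the median shifts of the fibroblast list were 0.0214 (before chemotherapy against control) and 0.0305 (after it), which follows from using the list's own mean, and that of smooth muscle before chemotherapy was 0.0148. Without the 2 biopsies the interferon list after chemotherapy against control was -0.374, and its single-biopsy range was -0.14 to 0.573. The cornifying list after chemotherapy against before ranged from -0.0196 to 0.711. The RNA ratio difference after chemotherapy against before was 0.0042 with GAPDH alone, and ranged from -0.121 to 0.0771 without single biopsies. Against control that range was -0.0233 to 0.175.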

Other observations

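All tests in this part were chosen after the results had been seen. In the basal keratinocyte list, the cells that renew the epithelium, 4 of 12 members were lower after chemotherapy began when adjusted over the list alone, and none over all genes. They were LAMB3 (log2 fold change -0.70), ITGB4 (-0.65), CAV1 (-0.42) and KRT5 (-0.26), of which LAMB3 and ITGB4 anchor basal cells to the basement membrane. These genes were picked after their values were seen, and the list as a whole did not pass (adjusted p = 0.0718). The mast cell list had 9 of 9 members lower, at 0.687-fold on average, and did not pass either (adjusted p = 0.0718). Cytosolic ribosomal protein genes gave means of 15.54 in all 3 groups.

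Other lists without a call included DNA damage repair (adjusted p = 0.822 after chemotherapy against before), NRF2 oxidative stress (0.0718), where SRXN1 was higher adjusted over the list alone (log2 fold change 0.60), NF-kB and inflammatory cytokines (0.221) and heat shock (0.86). The myeloid progenitor and blast list, markers of immature blood cells, had 4 of 6 members higher before chemotherapy than in controls, with a mean shift of 0.26 (adjusted p = 0.204, exact permutation p = 0.2 for the list mean).

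A hypothesis was that mitotic genes fell more than replication genes after chemotherapy began. The mitotic minus replication list mean was -0.17 ± 0.08 (SD, n = 4) before and -0.494 ± 0.187 (n = 4) after, a difference of -0.324 whose exact permutation p was 0.0571. In the 3 complete patients the difference was lower in 3 of 3, by -0.0543 to -0.622, but with 3 pairs a sign-flip test cannot give a p under 0.25. Neither form passed, so a selective fall of mitotic genes was neither shown nor excluded.

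For counts of calls, other splits of the same biopsies give the scale of chance. Before chemotherapy against control, the real split gave 0 genes (highest other 2), which all 35 splits reach by definition, so the gene count tests nothing, while for lists 1 of 35, the real one, reached 14 (highest other 10). This is the smallest share 35 splits can give, and several counts were tested. With an estimated correlation or in fry 0 of the 14 lists passed, so chance is not excluded for the number of lists. After chemotherapy against before, 4 of 35 splits gave at least 1 gene (highest other 5) and 33 of 35 gave at least 5 lists (highest other 15), so chance is not excluded for either count. Among the 8 splits that part all 3 pairs, the others gave no gene and up to 15 lists. After chemotherapy against control, 2 of 35 splits gave at least 7 genes and 16 of 35 at least 11 lists (highest other 16), so chance is not excluded for these counts. The other split with more genes gave 197, which points to a structure of the biopsies. What that structure is was not tested.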
